A study of Homo sapiens with 15 samples.

How the data were processed

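Total RNA from PC3 and DU145 prostate cancer cells was measured on 15 Affymetrix Human Gene 1.0 ST arrays. Per the labels, cells grew in RPMI 1640 with 10% serum and were transfected with 20 nM microRNA mimic (Ambion) using Lipofectamine 2000, the medium was changed after 6 h, and RNA was isolated with RNeasy after 48 h. For each array 100 ng of total RNA was labelled with the WT Expression kit. The deposited values are log2 levels that the authors made with the RMA16 option of GeneSpring GX 11.0, with the arrays of each cell line normalized separately. RMA as commonly defined corrects background, makes the arrays of a set share 1 distribution by quantile normalization and summarises probes by median polish. The option is understood to add 16 to the signal before the logarithm, which was not stated, and every deposited value lay above 4, the logarithm of 16. If so, folds of weakly expressed genes are understated. The genome build and probe set definition were not stated. The authors left out 1 DU145 scrambled array because of bad performance of the array. The values were used as deposited.

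The table held 28869 features. Of these, 19310 carried 1 gene symbol, 1752 carried several and 7807 carried none. Symbols were brought up to date through the Entrez gene number in the RefSeq gene table, which matched 19279 of the features with 1 symbol. Features of the same symbol were averaged, which left 18377 genes, 685 of them from more than 1 feature, with no filter on level. Features with several or no symbols were tested apart. Groups were untransfected, scrambled mimic, miR-224 mimic and miR-452 mimic in each line, with 2 arrays each except for 1 DU145 scrambled array, whose spread was taken to be that of the other DU145 groups. The number of arrays limits the precision, with 4 residual degrees of freedom in PC3, 3 in DU145 and 7 in the fit of both lines.

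Comparisons were made with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with 4 group means in 1 fit per line and empirical Bayes moderation. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 within the comparison. The difference between lines was a contrast of the log2 changes in a fit of all 15 arrays with 8 group means. Each mimic was compared with the scrambled mimic, the scrambled mimic with untransfected cells, and the mimics with each other. Correlations are across genes, which are not independent replicates. The correlation between mimics that share controls was set beside 50 simulated data sets of unchanged groups, and the expected overlap of calls is the product of the calls divided by the genes tested.

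The comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. Named for each mimic against the scrambled mimic were the 10 largest rises and 10 largest falls among genes that passed and whose mimic arrays all lay on the same side of all scrambled arrays, and fewer where fewer passed. The 5 largest in each direction were named for the scrambled mimic against untransfected cells and for miR-224 against miR-452. Also named were up to 4 members with the smallest p of each list described, every gene of the host locus, and up to 6 genes with the smallest p for the difference between lines. The examples of genes lower in both lines or higher with both mimics, and the genes in the plot of array values, were chosen after their values were seen.

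The 26 gene lists, with 448 of 495 entries measured, were the host locus of the microRNAs, reported miR-224 targets, reported miR-452 targets, interferon response, NF-kB and inflammatory cytokines, small RNA machinery, ATF4 and unfolded protein response, hypoxia and glycolysis, cholesterol biosynthesis, ribosomal proteins, DNA replication and G1/S, mitosis, DNA methylation and polycomb, immediate early and heat shock, p53 targets, apoptosis regulators, epithelial junction and keratin genes, mesenchymal markers, invasion proteases and integrins, TGF-beta and SMAD targets and Wnt feedback targets. Lists of androgen-regulated and luminal, neuroendocrine, fibroblast and stromal, leukocyte and endothelial genes stood for other cell types. The lists were written from general knowledge and not from these samples. The 25 lists with at least 5 measured genes were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and beside it with camera at an estimated correlation and with fry. Counts of members are given over all genes tested and adjusted over the list alone.

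Alternatives were the untransfected arrays, or the mean of both control groups, as the control, all 15 arrays in 1 fit, genes under percentile 20 of mean level left out, all features without averaging, quantile normalization within the line, limma with trend and robust moderation, the replicate letter of the array titles as a block, and each array left out in turn. A block with the letters of the DU145 miR-452 arrays crossed was added after seeing the data. A search of untranslated regions for seed sites of the microRNAs was planned and not run for lack of a genome sequence. The procedure was tested on simulated data with the spread and layout of these arrays. Of 18377 genes, 200 were changed for miR-224 against the scrambled mimic, 50 at each of 4 sizes. At smaller log2 changes of 0.4, 0.6 and 0.8 PC3 recovered 32%, 74% and 84% and DU145 2%, 24% and 48%. Over all 4 sizes, 4 of 145 calls were false in PC3 and 1 of 80 in DU145. Between the mimics 13 of 161 and 3 of 119 were false. Figures were drawn with Python 3.11.15.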

Results

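Gene expression was measured on 15 Affymetrix Human Gene 1.0 ST arrays, 8 from PC3 cells and 7 from DU145 cells. Both are prostate cancer cell lines, and the labels give a bone metastasis as the origin of PC3. Cells were left untransfected, or were transfected with a scrambled mimic, a miR-224 mimic or a miR-452 mimic at 20 nM, and RNA was taken after 48 h. A mimic is a synthetic double-stranded RNA that supplies the mature microRNA. Each group had 2 arrays except the DU145 scrambled group, which had 1. The deposited values ran from 4.49 to 14.18 on the log2 scale. The array median lay between 6.94 and 7.05 in PC3 and between 6.51 and 6.67 in DU145. Replicate arrays correlated with r between 0.992 and 0.998 across all features, and the number of arrays limits the precision. Changes are log2 differences ± the standard error from limma, with adjusted p over 18377 genes. The p-values measure only the spread between these arrays, and the labels do not say whether replicates were separate cultures. The series title concerns methylation of the locus that holds GABRE and both microRNAs, and each mimic comparison asks which transcripts change when 1 of these microRNAs is supplied.

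In PC3 cells, AXL, a receptor tyrosine kinase, was 2.97-fold higher with the miR-224 mimic than with the scrambled mimic (1.57 ± 0.086, adjusted p = 7.37e-06, n = 2 arrays in each group). PMAIP1, which encodes the pro-apoptotic protein NOXA, rose 2.54-fold (1.34 ± 0.085), and GBA2, a glucosylceramidase outside the lysosome, rose 2.52-fold (1.33 ± 0.097). The largest falls among mRNAs were CALB1, a calcium-binding protein, which fell by 1.62 ± 0.082 (adjusted p = 6.37e-06), and DPYSL2, a protein of axon growth, which fell by 1.45 ± 0.094. C12orf57 fell by 1.42 ± 0.14. The other large rises were SLC4A1AP (1.41 ± 0.12), RAB18, a small GTPase (1.40 ± 0.14), ENTPD7 (1.36 ± 0.093), CIAO2A (1.35 ± 0.16), RNF157 (1.33 ± 0.085), RMND5A (1.33 ± 0.15) and SFT2D2 (1.31 ± 0.100). Against untransfected cells, 6 of these 10 genes were also higher, with RAB18 at 0.66, ENTPD7 at 1.26 and GBA2 at 1.10. The 4 that did not pass there were AXL at 0.07, RNF157 at -0.03, SFT2D2 at -0.01 and CIAO2A at 0.34. Small noncoding RNA genes made up the other 7 of the 10 largest falls. These were RNU5D-1 (-2.15 ± 0.44), VTRNA1-1 (-1.68 ± 0.34), RNU4-2 (-1.54 ± 0.44), SCARNA4 (-1.50 ± 0.36), SNORA20 (-1.42 ± 0.42), SNORD104 (-1.40 ± 0.29) and RNVU1-15 (-1.32 ± 0.20). Of the 10, VTRNA1-1 (-1.01), RNU4-2 (-0.94), SCARNA4 (-0.95) and SNORA20 (-0.99) did not pass against untransfected cells.

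Of 29 DNA replication and G1/S genes, 13 fell, 0 rose and 16 did not pass in PC3 with miR-224 (camera adjusted p = 1.61e-06, and adjusted p = 0.64 with an estimated correlation). By limma 18 fell and 1 rose when adjusted over the list alone, as many as at an unadjusted p under 0.05. RRM2, a subunit of ribonucleotide reductase, fell by 0.92 ± 0.077, and the thymidylate synthase gene TYMS (-0.65 ± 0.079) and the replicative helicase genes MCM2 (-0.61 ± 0.083) and MCM5 (-0.55 ± 0.080) fell as well. Of 20 hypoxia and glycolysis genes, 5 fell and 0 rose, with 5 and 0 adjusted over the list alone and 10 and 0 at an unadjusted p under 0.05 (camera adjusted p = 6e-05, and adjusted p = 0.64 with an estimated correlation). They included PFKFB4 (-0.67 ± 0.081), PDK1 (-0.62 ± 0.078), ALDOC (-0.60 ± 0.083) and PFKFB3 (-0.35 ± 0.079), which act in glucose metabolism. Against untransfected cells the list did not pass, with 4 members lower (camera adjusted p = 0.185). Of 20 ribosomal protein genes, 7 fell and 0 rose, with 12 and 1 adjusted over the list alone (camera adjusted p = 0.000204, and adjusted p = 0.798 with an estimated correlation). Among them RPL10A changed by -0.56 ± 0.14, RPL11 by -0.43 ± 0.088, RPS19 by -0.31 ± 0.076 and RPL13 by -0.32 ± 0.082, and RPL13 stood at 0.02 against untransfected cells. Of 28 genes reported as miR-224 targets in earlier studies, 7 fell and 4 rose, with 7 and 5 adjusted over the list alone (camera adjusted p = 0.256, and adjusted p = 0.798 with an estimated correlation). API5, an inhibitor of apoptosis, fell by 0.88 ± 0.10, and TPD52, MBD2 and SMAD4 changed by -0.65 ± 0.081, -0.69 ± 0.083 and -0.49 ± 0.077.

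By limma, 2225 genes were higher and 855 lower with miR-224 than with the scrambled mimic in PC3, 33 and 26 of them by more than 2-fold. Against untransfected cells the split turned to 521 higher and 1259 lower. The total of 3080 became 1163 without miR-224 b and 1838 without scrambled c. The call held without each array in turn for 15 of the 20 genes with the largest changes. It was lost for RNU5D-1, SNORD104 and RPL11 without miR-224 b, for RPL10A also without scrambled c, for RPS19 and PFKFB3 without scrambled c or either miR-224 array, for RNU4-2 without miR-224 b or either scrambled array, for SCARNA4 without miR-224 a or either scrambled array, for SNORA20 without miR-224 b or any control array, and for RPL13 without any 1 of the scrambled and miR-224 arrays. The DNA replication and G1/S count of 13 became 8 without scrambled b, the hypoxia and glycolysis count of 5 became 3 without miR-224 b, and the count for ribosomal proteins of 7 became 4 and 2 without scrambled b or c and 3 and 0 without miR-224 a or b.

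In DU145 cells, AXL was 2.59-fold higher with miR-224 than on the scrambled array (1.37 ± 0.10, adjusted p = 0.00208, n = 2 against 1). RNF157, an E3 ubiquitin ligase, rose by 1.23 ± 0.099, ANKFY1 by 1.16 ± 0.10, and ABCA1, a cholesterol exporter, by 1.03 ± 0.12. NDUFA8, a subunit of mitochondrial complex I, fell by 1.42 ± 0.14 (adjusted p = 0.0022) and CYRIB, a regulator of actin through Rac1, fell by 1.40 ± 0.13. MTRR, methionine synthase reductase, fell by 1.27 ± 0.11, API5 fell by 1.22 ± 0.12, and the epithelial adhesion gene EPCAM dropped 2.3-fold (SE 0.21 on the log2 scale). The other named rises were NRBP1 (1.11 ± 0.11), KRT80 (1.07 ± 0.13), SFT2D2 (1.02 ± 0.18), DDAH1 (1.01 ± 0.10), MGAT4A (0.89 ± 0.16) and SCML2 (0.86 ± 0.12). Against untransfected cells, AXL stood at 0.16, RNF157 at 0.01, ANKFY1 at 0.16, KRT80 at 0.03 and MGAT4A at 0.03, none of which passed, while SFT2D2 was lower there (-0.63). The other named falls were SNORA14A (-1.81 ± 0.38), C12orf57 (-1.32 ± 0.12), RNU4-2 (-1.26 ± 0.25), SNORA21 (-1.25 ± 0.11) and FBXO27 (-1.23 ± 0.12), and all 10 named falls were also lower than in untransfected cells.

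Among 16 cholesterol biosynthesis genes, 3 fell and 0 rose in DU145 with miR-224, with 7 and 0 adjusted over the list alone (camera adjusted p = 5.45e-07, and adjusted p = 0.727 with an estimated correlation). These were HMGCS1 (-0.86 ± 0.11) and MSMO1 (-0.90 ± 0.15), enzymes of the pathway, and its transcription factor SREBF2 (-0.67 ± 0.10). Of 20 epithelial junction and keratin genes, EPCAM, CLDN1 (-0.65 ± 0.11) and KRT8 (-0.48 ± 0.10) fell and 0 rose, with 7 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.0457, and adjusted p = 0.727 with an estimated correlation). Of 29 DNA replication genes RRM2 (-0.85 ± 0.10) and MCM2 (-0.66 ± 0.10) fell, 2 also when adjusted over the list alone (camera adjusted p = 0.0457, and adjusted p = 0.727 with an estimated correlation). The median of the 29 mitosis genes was 0.15 and that of the 16 DNA methylation and polycomb genes 0.15, with camera adjusted p = 0.00713 for each, and adjusted p = 0.727 with an estimated correlation. No member of either list passed by limma. At an unadjusted p under 0.05, 8 mitosis genes were higher and 2 lower, and 5 and 1 of the methylation genes. Against untransfected cells both medians were below 0, at -0.20 for mitosis with 8 members lower (camera adjusted p = 0.000441, and adjusted p = 0.664 with an estimated correlation) and -0.08 for the methylation list (0.497). Adjusted over the list alone, 0 mitosis genes passed, and 1 methylation gene was higher and 1 lower. Of 28 reported miR-224 targets, 5 fell and 0 rose, with 5 and 1 adjusted over the list alone (camera adjusted p = 0.0513, and adjusted p = 0.727 with an estimated correlation), and these included API5, AP2M1 (-0.88 ± 0.10), TPD52 (-0.77 ± 0.10) and SMAD4 (-0.56 ± 0.11).

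By limma, 116 genes were higher and 241 lower with miR-224 in DU145, 8 and 30 by more than 2-fold. The total of 357 became 3850 against untransfected cells. It became 84 without miR-224 a, 82 without miR-224 c, 148 without either untransfected array and 968 without either miR-452 array. The call was lost for SFT2D2, SNORA14A, RNU4-2, MSMO1, SREBF2 and MCM2 without either miR-224 array, for KRT8, CLDN1 and SMAD4 without any 1 of the miR-224 and untransfected arrays, for MGAT4A and SCML2 without miR-224 a, and for EPCAM and TPD52 without miR-224 c. The cholesterol biosynthesis count of 3 became 1 without either miR-224 array and 5 without either miR-452 array, and the reported miR-224 targets that fell became 3 without miR-224 a or either untransfected array and 2 without miR-224 c. The count of epithelial junction and keratin genes became 1 without miR-224 a or either untransfected array, 0 without miR-224 c and 5 without either miR-452 array. The camera call ended for that list without miR-224 a (adjusted p = 0.0561) or either miR-452 array (0.0834), for DNA replication and G1/S without miR-224 c (0.225) or either miR-452 array (0.052), and for mitosis without miR-224 a (0.168). Without either miR-452 array 1 mitosis gene rose, and of DNA methylation and polycomb genes 1 rose and 1 fell. After quantile normalization MGAT4A and SNORA14A no longer passed, nor did the G1/S and epithelial lists, with 1 epithelial rise.

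The miR-224 changes in the 2 lines correlated across 18377 genes with r = 0.49 (Spearman 0.40), although genes are not independent replicates. Of the 3080 genes called in PC3, 80.2% had the same sign in DU145. In both lines 79 genes rose (14.0 by independent calls), 160 fell (11.2) and 4 passed in opposite directions. Against untransfected cells these were 54 (28.4), 715 (195) and 55, so the excess of rises depended on the control. The genes lower in both included C12orf57, CYRIB (-1.01 in PC3), NDUFA8 (-0.97 in PC3) and API5. The change itself differed between the lines for 212 genes, 167 higher and 45 lower in PC3. CALB1 fell in PC3 and stood at -0.04 in DU145 (difference -1.58 ± 0.12, adjusted p = 4.37e-05). THBS1, an inhibitor of angiogenesis, fell in PC3 (-0.81) and rose in DU145 (0.62, but -0.12 against untransfected cells), a difference of -1.43 ± 0.13. DUSP6, a phosphatase of ERK, rose in PC3 (0.86) and fell in DU145 (-0.66, a call lost after quantile normalization), a difference of 1.52 ± 0.16. CTH, an enzyme of cysteine synthesis, fell in PC3 (-1.21) and stood at 0.28 in DU145. TBXAS1 rose in PC3 (1.14) and stood at -0.08 in DU145, and ELK3 stood at 0.22 in PC3 and fell in DU145 (-0.91). These 6 differences passed without each array in turn except the single DU145 scrambled array, without which they cannot be formed, while the DU145 calls of THBS1 and DUSP6 were lost without any 1 of the DU145 untransfected and miR-224 arrays. By camera the mitosis list was lower in PC3 than in DU145, with a median difference of -0.19 and 1 of 29 members passing, 1 adjusted over the list alone (camera adjusted p = 1.17e-06, and adjusted p = 0.638 with an estimated correlation). So was the hypoxia and glycolysis list (-0.11, camera adjusted p = 0.00593), where ALDOC passed and 2 did adjusted over the list alone. In the DNA replication and G1/S list (-0.09, camera adjusted p = 0.00257) 0 members passed by limma, also over the list alone, and 4 were lower at an unadjusted p under 0.05, and both lists had adjusted p = 0.638 with an estimated correlation. The count of 212 became 47 without PC3 miR-224 b, 56 without PC3 scrambled c, 75 and 51 without DU145 miR-224 a or c, 93 without either DU145 untransfected array and 411 without either DU145 miR-452 array. Against untransfected cells it was 942.

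**Figure D1:**
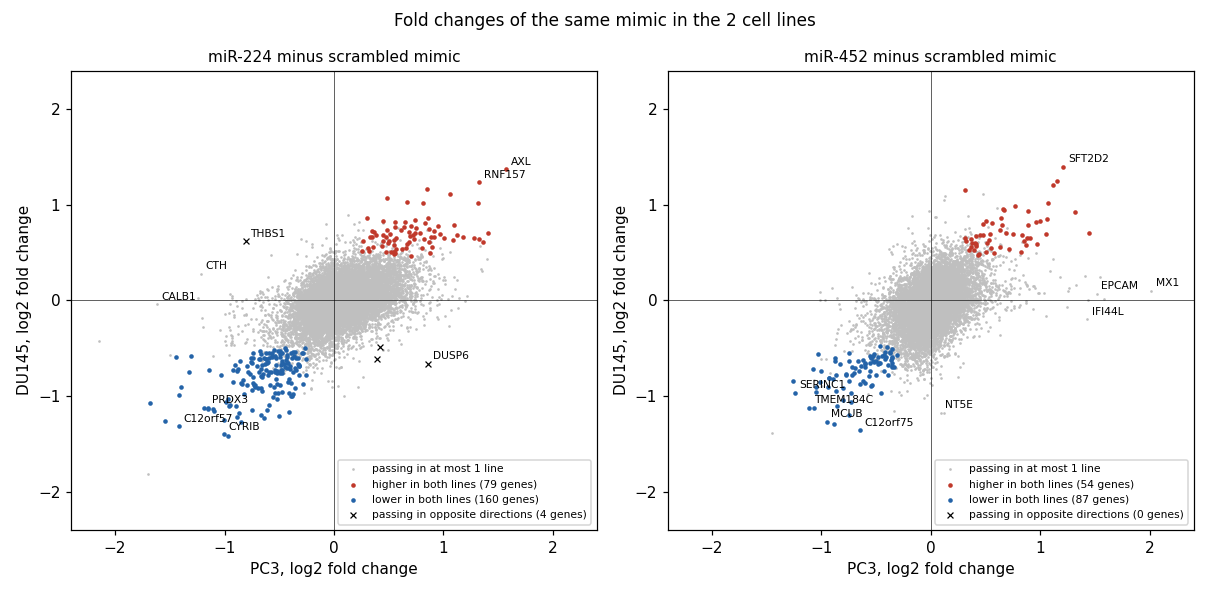
Log2 fold change of each gene in PC3 (horizontal) and DU145 (vertical) for miR-224 (left) and miR-452 (right) minus the scrambled mimic, with 1 point per gene and colour for genes passing in both lines. In both lines 79 genes are higher and 160 lower for miR-224 and 54 and 87 for miR-452. Against untransfected cells, not drawn, these are 54 (28.4 expected) and 715, and 480 and 1616.

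In PC3 cells, miR-452 raised genes of the interferon response. MX1, an antiviral GTPase, rose 4.04-fold over the scrambled mimic (2.01 ± 0.14, adjusted p = 3.58e-05, n = 2 arrays in each group). The oligoadenylate synthetase genes OAS1 and OAS2, sensors of double-stranded RNA, rose by 1.58 ± 0.11 and 1.54 ± 0.11. IFIT1 rose by 1.27 ± 0.086, IFI44L by 1.43 ± 0.096, IFI44 by 1.41 ± 0.12, IFITM1 by 1.44 ± 0.15 and SAMD9 by 1.45 ± 0.10. Of 29 interferon response genes, 21 rose, 0 fell and 8 did not pass, 24 rising and 0 falling when adjusted over the list alone, and 0 lower at an unadjusted p under 0.05. The list median was 0.71 (camera adjusted p = 1.84e-32, and adjusted p = 0.229 with an estimated correlation). By fry, which asks whether the members move on balance in 1 direction, the adjusted p was 0.0079. EPCAM rose 2.86-fold (1.52 ± 0.13), ARB2BP by 1.33 ± 0.11 and AXL by 1.32 ± 0.086. Against untransfected cells AXL stood at -0.18, while the other 9 named rises were also higher there. COQ10B, a coenzyme Q binding protein, fell by 1.26 ± 0.11 (adjusted p = 9.62e-05), SERINC1 fell by 1.24 ± 0.10 and TMEM184C fell by 1.11 ± 0.086. The other named falls were ARF4, a small GTPase of the Golgi (-1.07 ± 0.085), IFT22 (-1.06 ± 0.084), OAZ2 (-1.05 ± 0.15), DR1 (-1.05 ± 0.091), ADD3 (-1.03 ± 0.085), RELN (-1.01 ± 0.092) and MLLT11 (-1.01 ± 0.081). All 10 named falls were also lower than in untransfected cells.

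Other lists moved less in PC3 with miR-452. Of 20 hypoxia and glycolysis genes, 5 fell and 0 rose, with 6 and 0 adjusted over the list alone (camera adjusted p = 4.68e-06, and adjusted p = 0.462 with an estimated correlation), among them BNIP3 (-0.56 ± 0.074), PGK1 (-0.52 ± 0.080), ALDOC (-0.43 ± 0.083) and PFKFB4 (-0.36 ± 0.081). Against untransfected cells PGK1 (-0.46) and ALDOC (-0.48) were lower, BNIP3 stood at -0.21 and PFKFB4 at -0.01 without passing, and the list did not pass, with 3 members lower and 2 higher (camera adjusted p = 0.344). Of 20 epithelial genes, EPCAM and KRT7 (0.49 ± 0.086) rose and 0 fell, with 6 rises adjusted over the list alone (camera adjusted p = 7.19e-05, and adjusted p = 0.467 with an estimated correlation). Of 29 DNA replication genes, 4 rose and 0 fell, with 5 rises adjusted over the list alone (camera adjusted p = 0.0236, and adjusted p = 0.595 with an estimated correlation). They were CDC25A (0.42 ± 0.089), CCNE2 (0.36 ± 0.083), MCM6 (0.33 ± 0.082) and RFC4 (0.31 ± 0.081). Against untransfected cells CCNE2 stood at -0.36, MCM6 at -0.36 and RFC4 at -0.09, and the list turned direction there, with a median of -0.25, 14 members lower and 0 higher (camera adjusted p = 5.05e-06, and adjusted p = 0.4 with an estimated correlation). Of 21 ATF4 and unfolded protein response genes, 4 fell and 1 rose, with 6 and 2 adjusted over the list alone (camera adjusted p = 0.0331, and adjusted p = 0.595 with an estimated correlation). PDIA4 (-0.54 ± 0.10), ATF4 (-0.41 ± 0.094) and HERPUD1 (-0.35 ± 0.080) were among the falls, and the cystine transporter gene SLC7A11 was the rise (0.32 ± 0.075, but -0.02 against untransfected cells). Of 18 NF-kB and cytokine genes, TNFAIP3 rose (0.54 ± 0.11) and 0 fell, with 4 rises adjusted over the list alone (camera adjusted p = 0.0346, and adjusted p = 0.595 with an estimated correlation). Of 10 reported miR-452 targets, the ubiquitin ligase gene WWP1 (-0.87 ± 0.082) and EPB41L3 (-0.59 ± 0.082) fell and CPEB3 rose (0.53 ± 0.086), with 4 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.0448, and adjusted p = 0.595 with an estimated correlation). By limma no interferon, hypoxia, epithelial, replication or NF-kB gene passed in the other direction, and none did so at an unadjusted p under 0.05.

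By limma, 531 genes were higher and 428 lower with miR-452 in PC3, 25 and 12 by more than 2-fold. The call of each of the 20 genes with the largest changes held without each array in turn. The total of 959 became 585 without scrambled b, 480 without miR-452 b, 469 without miR-452 c and 4080 against untransfected cells. The call was lost for KRT7 without miR-452 c, for ALDOC without scrambled b or miR-452 b, for ATF4, PDIA4 and CCNE2 without scrambled b or either miR-452 array, for TNFAIP3 and CDC25A without scrambled c or either miR-452 array, for HERPUD1 and PFKFB4 without any 1 of the scrambled and miR-452 arrays, for MCM6 and SLC7A11 without any 1 of the transfected arrays, and for RFC4 without any 1 of the 8 arrays. The DNA replication and G1/S count of 4 became 1 without either scrambled array or miR-452 c, 0 without miR-452 b and 2 without either miR-224 array, and the hypoxia and glycolysis count of 5 became 2 without scrambled b or miR-452 b and 3 without miR-452 c. The falls of the ATF4 and unfolded protein response list became 1 and 2 without scrambled b or c and 0 and 1 without miR-452 b or c. The camera call ended for that list without scrambled b (adjusted p = 0.13), for DNA replication and G1/S without scrambled c (0.107), for NF-kB and inflammatory cytokines without scrambled b or c or miR-452 b (0.0665, 0.073 and 0.184), and for reported miR-452 targets without scrambled b or c or miR-452 c (0.12, 0.0568 and 0.0921). After quantile normalization the ATF4, NF-kB and reported target lists no longer passed, with 2 NF-kB rises, and against untransfected cells the ATF4 (camera adjusted p = 0.29) and reported target lists (0.296) did not.

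In DU145 cells, miR-452 raised ANKRD1, a transcriptional cofactor gene, 2.17-fold over the scrambled array (1.12 ± 0.12, adjusted p = 0.00629, n = 2 against 1), and DDAH1, which degrades methylated arginine, 2.3-fold (SE 0.10 on the log2 scale). SFT2D2 rose by 1.39 ± 0.18, KRT80 by 1.25 ± 0.13 and SLC7A11 by 1.16 ± 0.10. C12orf75 fell by 1.36 ± 0.12 (adjusted p = 0.00335), the calcium sensor gene NCS1 fell by 1.29 ± 0.13, and MCUB, which encodes a subunit of the mitochondrial calcium uniporter, fell by 1.27 ± 0.15. NT5E, the ecto-nucleotidase CD73, fell by 1.17 ± 0.14. The other named rises were ROCK1P1 (1.09 ± 0.24), RRAGC (1.01 ± 0.14), PMAIP1 (0.99 ± 0.16), DCTN5 (0.95 ± 0.15) and MMADHC (0.94 ± 0.18). Against untransfected cells SFT2D2 stood at -0.26, RRAGC at -0.04, DCTN5 at 0.06, MMADHC at 0.13 and KRT80 at 0.22, none of which passed. The other named falls were FBXO27 (-1.19 ± 0.12), SNORA21 (-1.18 ± 0.11), WDR54 (-1.16 ± 0.10), IFT22 (-1.13 ± 0.11), TMEM184C (-1.12 ± 0.12) and DCAKD (-1.11 ± 0.14), and all 10 named falls were also lower than in untransfected cells.

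Of 16 cholesterol biosynthesis genes, FDPS (-0.69 ± 0.11) and INSIG1 (-0.69 ± 0.11) fell and 0 rose in DU145 with miR-452, with 2 falls adjusted over the list alone (camera adjusted p = 0.00602, and adjusted p = 0.99 with an estimated correlation). Of 15 immediate early and heat shock genes, EGR1 fell (-0.68 ± 0.11) and 0 rose, with 5 falls adjusted over the list alone (camera adjusted p = 0.00602, and adjusted p = 0.99 with an estimated correlation). Of 20 hypoxia genes 0 passed by limma, 5 were lower and 1 higher at an unadjusted p under 0.05, and 3 fell when adjusted over the list alone (camera adjusted p = 0.0421, and adjusted p = 0.99 with an estimated correlation). Of 29 interferon genes 1 rose and 0 fell (camera adjusted p = 0.352, and adjusted p = 0.99 with an estimated correlation), with 3 higher and 0 lower at an unadjusted p under 0.05. None of the 10 reported miR-452 targets passed, with 1 higher and 1 lower at an unadjusted p under 0.05 and the same numbers adjusted over the list alone (camera adjusted p = 0.975, and adjusted p = 0.99 with an estimated correlation). WWP1 stood at -0.40 ± 0.11 and CPEB3 at 0.38 ± 0.10. By limma, 106 genes were higher and 280 lower, 7 and 13 by more than 2-fold. Without miR-452 a 57.6% of the calls were higher, and without miR-452 c 18.7%. After quantile normalization the split was 284 and 408, or 41.0% higher in place of 27.5%, and ROCK1P1 and the hypoxia list, with 1 fall, no longer passed. The total of 386 became 114 without either untransfected array, 244 without either miR-224 array, 863 without miR-452 a, 1211 without miR-452 c and 5178 against untransfected cells. ROCK1P1 lost its call without either untransfected array or miR-452 a, and MMADHC, FDPS and INSIG1 lost theirs without either untransfected array. Without miR-452 c the cholesterol biosynthesis falls became 4, the immediate early and heat shock falls 4 and the hypoxia and glycolysis falls 5, and without either untransfected array the cholesterol falls became 0. Without miR-452 a the camera adjusted p of these lists was 0.176, 0.176 and 0.213, and against untransfected cells that of the immediate early and hypoxia lists was 0.147 and 0.145. That of the hypoxia list was 0.0559 without either untransfected array and 0.0503 without either miR-224 array.

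The miR-452 changes in the 2 lines correlated across genes with r = 0.45 (Spearman 0.38), and 82.0% of the PC3 calls had the same sign in DU145. In both lines 54 genes rose, where independent calls would give 3.06, and 87 fell, where they would give 6.52. None passed in opposite directions by limma at adjusted p under 0.05. Against untransfected cells, which adds the effect of transfection, 480 rose in both lines (124 by independent calls), 1616 fell (514) and 70 passed in opposite directions. The genes lower in both included TMEM184C, IFT22, SERINC1 (-0.97 in DU145), COQ10B (-0.85 in DU145) and MCUB (-0.95 in PC3). The change differed between the lines for 114 genes, 87 higher and 27 lower in PC3. MX1 stood at 0.10 in DU145, a difference of 1.91 ± 0.21 (adjusted p = 0.00142), OAS1 at 0.01, a difference of 1.57 ± 0.17, and IFI44L at -0.20, a difference of 1.63 ± 0.16. The interferon list was higher in PC3 than in DU145 by a median of 0.74, with 13 of 29 members passing and 21 when adjusted over the list alone (camera adjusted p = 3.96e-31, and adjusted p = 0.0312 with an estimated correlation). The camera test also placed the epithelial list higher in PC3, by a median of 0.26 (adjusted p = 0.000843) with 3 members passing, and the immediate early and heat shock list by 0.32 (1.64e-05) with 1, each with adjusted p = 0.195 with an estimated correlation. Adjusted over the list alone, 5 epithelial genes were higher and 1 lower, and 8 immediate early genes were higher. IL13RA2, an interleukin receptor gene, rose in PC3 (1.25) and stood at -0.07 in DU145, CD68 rose in PC3 (0.63) and stood at -0.36, and NT5E stood at 0.09 in PC3 (-0.35 against untransfected cells, where it was lower), a difference of 1.27 ± 0.15. These 6 differences passed without any 1 of the 14 arrays other than the DU145 scrambled array, on which all of them rest. The count of 114 became 64 and 26 without PC3 scrambled b or c, 72 without either PC3 miR-224 array, 26 and 46 without PC3 miR-452 b or c, 34 without either DU145 untransfected array and 263 without DU145 miR-452 c. Against untransfected cells it was 529.

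**Figure D2:**
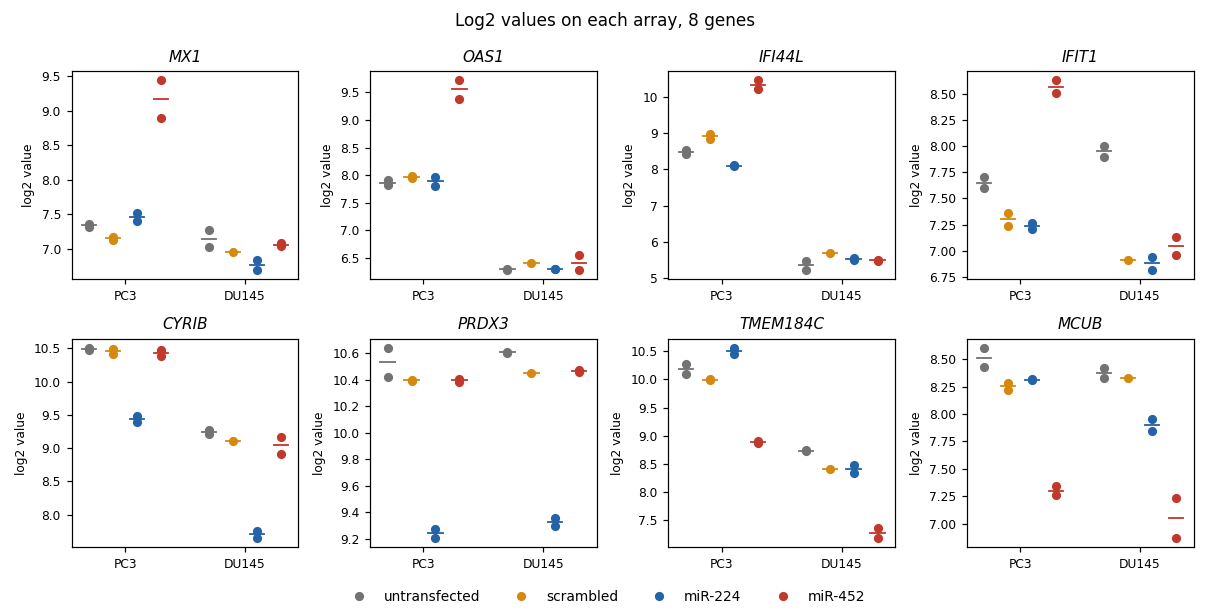
Deposited log2 value (vertical, with a range of its own for each gene) on each array for 4 interferon response genes and 4 genes lower with 1 mimic in both lines, by cell line and group. Points are single arrays and lines are group means, and the genes were picked for the plot after their values were seen. With miR-452, MX1 averaged 9.17 in PC3 and 7.06 in DU145.

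The comparison of the scrambled mimic with untransfected cells asks what transfection of an unrelated mimic changes. In PC3 AXL was 2.82-fold lower than in untransfected cells (SE 0.086 on the log2 scale, adjusted p = 2.51e-05, n = 2 arrays in each group). RNF157 changed by -1.36 ± 0.085, SFT2D2 by -1.33 ± 0.100, SNORD78 by -1.22 ± 0.18 and SNORD45B by -1.02 ± 0.16. The largest rises were RGS4, a regulator of G protein signalling (1.04 ± 0.076), RNU4-1 (0.85 ± 0.24), OR5M10 (0.83 ± 0.23), CTH (0.80 ± 0.095) and BRINP2 (0.77 ± 0.095). In DU145 (n = 1 against 2) the same 3 mRNAs were among the 5 largest falls, with SFT2D2 at -1.65 ± 0.18, RNF157 at -1.23 ± 0.099 and AXL at -1.21 ± 0.10, beside CCDC80 (-1.26 ± 0.14) and SNORD58A (-1.20 ± 0.27). RNU4-1 (0.95 ± 0.14), BHLHA9 (0.89 ± 0.21), KRTAP5-4 (0.88 ± 0.19), LINC01783 (0.88 ± 0.13) and FUT5 (0.85 ± 0.17) were the largest rises there.

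Cell cycle genes were lower with the scrambled mimic than in untransfected PC3 cells. Of 29 mitosis genes 22 fell and 0 rose, with a median of -0.36, and 26 fell when adjusted over the list alone (camera adjusted p = 7.62e-12, and adjusted p = 0.429 with an estimated correlation). They included CDK1 (-0.60 ± 0.10), AURKA (-0.43 ± 0.075), KIF11 (-0.58 ± 0.10) and HMMR (-0.55 ± 0.085). Of 29 DNA replication genes 18 fell and 0 rose, with 23 falls adjusted over the list alone (camera adjusted p = 7.62e-12, and adjusted p = 0.429 with an estimated correlation), among them CLSPN (-0.75 ± 0.10), CCNE2 (-0.72 ± 0.083), MCM6 (-0.70 ± 0.082) and TYMS (-0.55 ± 0.079). Of 16 DNA methylation and polycomb genes 5 fell and 0 rose, with 5 falls adjusted over the list alone (camera adjusted p = 0.0494, and adjusted p = 0.886 with an estimated correlation), including EZH2 (-0.45 ± 0.094), UHRF1 (-0.40 ± 0.10), DNMT1 (-0.38 ± 0.079) and SUZ12 (-0.33 ± 0.082). Of 20 hypoxia genes 3 rose and 0 fell, NDRG1 (0.50 ± 0.081), BNIP3 (0.35 ± 0.074) and PFKFB4 (0.35 ± 0.081), with 6 rises adjusted over the list alone (camera adjusted p = 0.0221, and adjusted p = 0.886 with an estimated correlation). No mitosis, replication, methylation or hypoxia gene passed in the opposite direction by limma, also at an unadjusted p under 0.05. The standard deviation of values on an array was 1.81 and 1.78 on the untransfected PC3 arrays and 1.75 and 1.71 on the scrambled ones, and 1.65 and 1.65 against 1.57 in DU145.

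In DU145 11 of 29 mitosis genes fell, with a median of -0.37 and 20 falls adjusted over the list alone (camera adjusted p = 1.53e-07, and adjusted p = 0.809 with an estimated correlation), CENPE (-0.78 ± 0.18), ASPM (-0.65 ± 0.13), KIF11 (-0.53 ± 0.11) and CENPF (-0.51 ± 0.11) among them. Of 29 replication genes 4 fell, with 4 adjusted over the list alone (camera adjusted p = 0.00539, and adjusted p = 0.809 with an estimated correlation), namely CLSPN (-0.69 ± 0.16), MCM6 (-0.64 ± 0.15), POLA1 (-0.60 ± 0.12) and CDC6 (-0.56 ± 0.11). Of 29 interferon genes 9 fell and 0 rose, with 12 falls and 3 rises adjusted over the list alone (camera adjusted p = 0.0205, and adjusted p = 0.809 with an estimated correlation), and IFIT1 (-1.04 ± 0.12), SAMD9 (-1.04 ± 0.13), RIGI (-0.82 ± 0.12) and IFIT2 (-0.74 ± 0.11) led. Of 14 small RNA machinery genes AGO3 (-0.62 ± 0.12), DROSHA (-0.59 ± 0.13) and AGO4 (-0.45 ± 0.10) fell, with 7 falls adjusted over the list alone (camera adjusted p = 0.00539, and adjusted p = 0.809 with an estimated correlation). Of 16 DNA methylation genes TET1 (-0.49 ± 0.13) and KDM6A (-0.46 ± 0.12) fell, with 7 adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.809 with an estimated correlation). The 12 fibroblast markers had a median of 0.23 (camera adjusted p = 0.014, and adjusted p = 0.809 with an estimated correlation), and by limma 0 of them passed, 0 adjusted over the list alone and 3 higher at an unadjusted p under 0.05.

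By limma, 611 genes were higher and 2007 lower with the scrambled mimic in PC3, and 478 and 1694 in DU145. The changes correlated across genes with r = 0.73 between the lines, 94.0% of the PC3 calls had the same sign in DU145, and 849 genes fell in both where independent calls would give 185. The change differed between the lines for 38 genes. By camera the interferon list was higher in PC3 than in DU145 (0.05, adjusted p = 0.00706), with 2 members passing and 7 adjusted over the list alone. The hypoxia list was also higher (0.16, 0.00294) and the G1/S list lower (-0.13, 0.00294), with 0 members of either passing by limma, also over the list alone, and 4 of each at an unadjusted p under 0.05. Each of the 3 lists had adjusted p = 0.764 with an estimated correlation. The calls of RGS4, CTH, BRINP2, AXL, RNF157, SFT2D2, SNORD78, MCM6 and CCNE2 in PC3 held without each array in turn. The other PC3 genes named for this comparison were lost without untransfected b, and of these BNIP3, PFKFB4, DNMT1 and EZH2 also without scrambled c, UHRF1 and OR5M10 without untransfected c or scrambled c, SUZ12 without either scrambled array, and RNU4-1 without untransfected c or either scrambled array. The PC3 total of 2618 became 82 without untransfected b and 504 without scrambled c. Without these arrays in the same order the mitosis count of 22 became 0 and 4, the DNA replication and G1/S count 2 and 5, the hypoxia and glycolysis count 0 and 1, and the DNA methylation and polycomb count 0 for both, while the mitosis median stayed at -0.31 without untransfected b. The camera call ended for hypoxia and glycolysis without untransfected c or scrambled b (adjusted p = 0.0927 and 0.116), and for DNA methylation and polycomb without untransfected c, scrambled c or either miR-224 array (0.11, 0.252 and 0.0644). In DU145 every gene named for this comparison was lost without untransfected b, all but SFT2D2, RNF157 and AXL also without untransfected c, and TET1 and KDM6A also without either miR-224 array. The DU145 total of 2172 became 0 by limma without untransfected b (3705 at an unadjusted p under 0.05), 4 without untransfected c and 5649 without either miR-452 array. The members of its lists that passed became 0 without either untransfected array, and without either miR-452 array 21 for mitosis, 7 for DNA replication and G1/S, 13 falls and 3 rises for the interferon response, 7 for small RNA machinery and 8 for DNA methylation and polycomb, with 3 rises among fibroblast and stromal markers. Without either miR-224 array the mitosis count there was 4 and the methylation count 0. After quantile normalization the mitosis falls became 14 in PC3 and 3 in DU145, with medians of -0.25 and -0.26, and the replication falls 11 and 1. The hypoxia rises in PC3 became 5 and the methylation falls in DU145 0. The DU145 total was then 1056, the replication, small RNA and fibroblast lists in DU145 and the methylation list in PC3 no longer passed, and the calls of OR5M10 and SUZ12 in PC3 and of BHLHA9, KRTAP5-4, SNORD58A, TET1, KDM6A, MCM6, POLA1, CLSPN and CENPE in DU145 were lost.

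**Figure D3:**
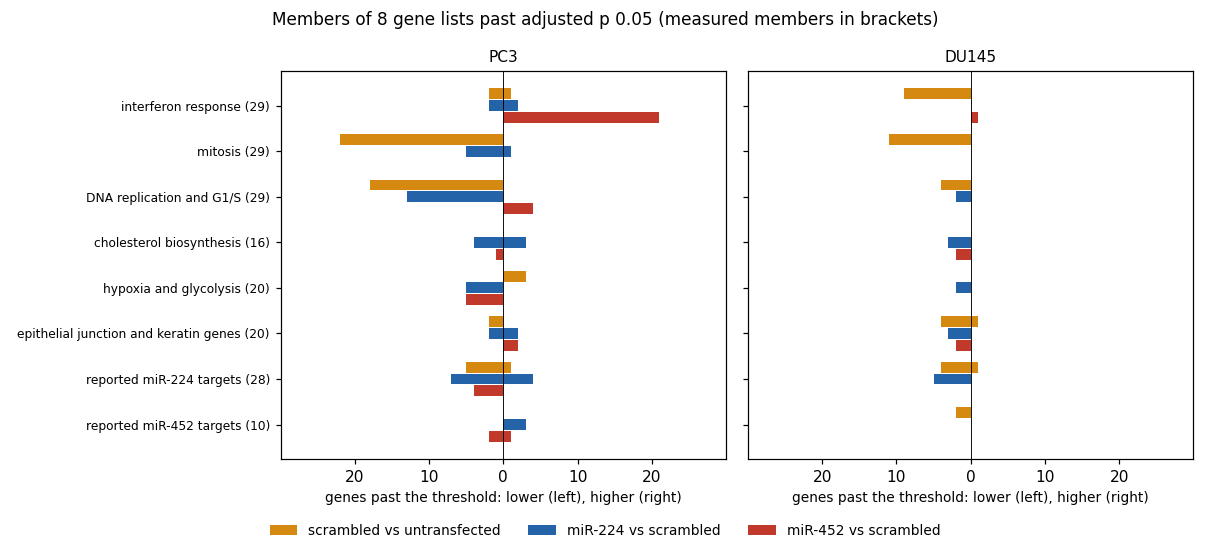
Number of members of 8 gene lists past adjusted p 0.05 (horizontal, lower to the left and higher to the right) in PC3 and DU145, with 1 bar per comparison and the number of measured members in brackets. With miR-452 in PC3, 21 of 29 interferon genes are higher, and with the scrambled mimic 22 of 29 mitosis genes are lower than in untransfected cells.

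Set against each other in PC3, miR-224 and miR-452 differed most at COQ10B (1.87 ± 0.11 for miR-224 minus miR-452), SERINC1 (1.78 ± 0.10), GBA2 (1.69 ± 0.097), TMEM184C (1.61 ± 0.086) and SPARC, a matrix protein (1.44 ± 0.10), which were higher with miR-224. IFI44L (-2.24 ± 0.096), EPCAM (-2.02 ± 0.13), MX1 (-1.71 ± 0.14), OAS1 (-1.67 ± 0.11) and RNU5D-1 (-1.64 ± 0.44) were lower. Of 29 interferon genes 23 were lower and 0 higher with miR-224, 25 lower when adjusted over the list alone (camera adjusted p = 6.82e-22, and adjusted p = 0.296 with an estimated correlation). Of 29 replication genes 17 were lower, 21 adjusted over the list alone (camera adjusted p = 3.57e-11, and adjusted p = 0.296 with an estimated correlation), led by RRM2 (-0.76 ± 0.077), CCNE2 (-0.75 ± 0.083) and TYMS (-0.71 ± 0.079). Of 20 epithelial genes 6 were lower and 1 higher, 7 and 1 adjusted over the list alone (camera adjusted p = 0.00249, and adjusted p = 0.597 with an estimated correlation), with KRT7 at -1.12 ± 0.086 and the tight junction gene CLDN4 at 0.56 ± 0.090. Of 21 ATF4 and unfolded protein response genes 7 were higher and 2 lower, 8 and 2 adjusted over the list alone (camera adjusted p = 0.0147, and adjusted p = 0.634 with an estimated correlation), with the chaperone gene HSPA5 at 0.59 ± 0.092. Of 20 ribosomal genes 3 were lower, 5 adjusted over the list alone (camera adjusted p = 0.00803, and adjusted p = 0.634 with an estimated correlation), of 18 NF-kB genes 4 were lower and 1 higher, 7 and 2 adjusted over the list alone (camera adjusted p = 0.0407, and adjusted p = 0.597 with an estimated correlation), and of 10 leukocyte markers CD68 (-0.78 ± 0.079) was lower, 1 also adjusted over the list alone (camera adjusted p = 0.0334, and adjusted p = 0.42 with an estimated correlation). Cytokine genes CXCL8 (-0.55 ± 0.093) and IL6 (-0.48 ± 0.088) were lower and LIF higher (0.68 ± 0.10). Of the reported targets, API5 was lower with miR-224 (-0.84 ± 0.10) and WWP1 lower with miR-452, 0.90 ± 0.082 for miR-224 minus miR-452. The DNA replication and G1/S count of 17 became 11 without miR-224 a or miR-452 b. The falls among epithelial junction and keratin genes became 3 without miR-224 a or miR-452 c and 2 without miR-224 b or miR-452 b, and the rises of the ATF4 and unfolded protein response list became 4 without miR-224 b. For ribosomal proteins the count became 0 without miR-224 b or miR-452 c and 5 without miR-452 b or either scrambled array. The camera call ended without miR-224 b for the ATF4 and unfolded protein response (adjusted p = 0.0676), without miR-224 b or miR-452 c for ribosomal proteins (0.0715 and 0.1) and leukocyte markers (0.0715 and 0.131), and without miR-224 a, miR-224 b or miR-452 b for NF-kB and inflammatory cytokines (0.0599, 0.0676 and 0.145). After quantile normalization the ATF4, leukocyte and NF-kB lists no longer passed, and the ribosomal count became 5.

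In DU145, DCAKD (1.45 ± 0.11), MYBL1 (1.34 ± 0.11), IGF2BP2 (1.30 ± 0.085), GNA12 (1.27 ± 0.083) and TIMP2, a protease inhibitor (1.25 ± 0.12), were higher with miR-224 than with miR-452. ANKRD1 (-1.64 ± 0.100), API5 (-1.51 ± 0.10), MTRR (-1.47 ± 0.087), CYRIB (-1.33 ± 0.10) and NECAP1 (-1.31 ± 0.13) were lower. Of 29 mitosis genes 5 were higher and 1 lower, 11 and 1 adjusted over the list alone (camera adjusted p = 0.00211, and adjusted p = 0.802 with an estimated correlation), with KIF20A at 0.62 ± 0.10 and BUB1 at 0.58 ± 0.11. Of 29 replication genes 3 were lower, 4 adjusted over the list alone, and of 29 interferon genes 2, with 3 adjusted over the list alone (camera adjusted p = 0.00211 for each, and adjusted p = 0.802 with an estimated correlation). RRM2 stood at -0.68 ± 0.083 and SAMD9 at -0.71 ± 0.11. By limma, 2299 genes were higher and 1101 lower with miR-224 in PC3, and 649 and 437 in DU145. In both lines 303 genes were higher and 218 lower, where independent calls would give 81.2 and 26.2, and 28 passed in opposite directions. The PC3 total of 3400 became 1642 without miR-224 b and 1787 without miR-452 c. The DU145 total of 1086 became 324 and 254 without miR-224 a or c, 612 without either untransfected array and 2152 without miR-452 c. RNU5D-1 lost its call in PC3 without miR-224 b or miR-452 c, and the other 19 of the largest differences kept theirs without each array in turn. In DU145 BUB1 lost its call without either miR-224 array, KIF20A without miR-224 a and SAMD9 without miR-224 c, and the mitosis count of higher genes became 0 and 2 without miR-224 a or c 12 without miR-452 c and 9 after quantile normalization. The DNA replication and G1/S count became 1 without either miR-224 or untransfected array and 5 without miR-452 a, and the interferon response count 0 without miR-224 c and 1 without miR-224 a, miR-452 c or either untransfected array. The DU145 camera call ended for mitosis without miR-224 a or miR-452 a (adjusted p = 0.161 and 0.395) and without miR-452 c for DNA replication and G1/S (0.389) and the interferon response (0.0621).

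Both mimics were compared with the same scrambled arrays, and in PC3 their changes correlated across genes with r = 0.26, while simulated unchanged groups against shared controls gave 0.50. The covariance was 0.0117 against a simulated 0.00461, and in DU145, where r was 0.52 against a simulated 0.67, it was 0.0215 against 0.0106. With scrambled arrays as the control of miR-224 and untransfected arrays as that of miR-452, r was -0.31 in PC3 and -0.025 in DU145, and with the controls exchanged it was 0.097 and -0.020. In PC3 251 genes rose and 74 fell with both mimics, where independent calls would give 64.3 and 19.9, and in DU145 41 and 65, where they would give 0.669 and 3.67. In opposite directions 80 genes rose with miR-224 and fell with miR-452 in PC3 and 29 the reverse, where independent calls would give 51.8 and 24.7, and 1 and 0 in DU145. Independent calls are not the value without change when controls are shared, and simulated unchanged groups gave 0.1 calls of the same sign on average in PC3 and 0.02 in DU145 over 18377 genes. Among the genes higher with both mimics than with the scrambled mimic were AXL in PC3 and SFT2D2, KRT80 and DDAH1 in DU145. Against untransfected cells AXL stood at 0.07 with miR-224 and -0.18 with miR-452, and KRT80 at 0.03 and 0.22, SFT2D2 was lower with miR-224 (-0.63) and stood at -0.26 with miR-452, and DDAH1 was higher with both (0.63 and 0.82).

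The host gene GABRE and its neighbours GABRA3 and GABRQ did not pass in any comparison. GABRE averaged 5.83 with the scrambled mimic in PC3 and 5.47 in DU145, and with miR-224 it stood at -0.10 ± 0.081 and 0.09 ± 0.12 relative to them. With miR-452 it stood at -0.08 ± 0.081 and 0.08 ± 0.12, GABRQ at 0.01 ± 0.090 and -0.06 ± 0.099, and GABRA3 at -0.02 ± 0.083 with miR-224 in PC3 and -0.14 ± 0.11 with miR-452 in DU145. The remaining lists did not pass camera against the scrambled mimic or between the mimics within a line, and their counts are given for miR-224 in PC3, the comparison with the scrambled mimic in which most genes passed. Of mesenchymal markers 6 rose and 3 fell of 19 (7 and 3 adjusted over the list alone, camera adjusted p = 0.208), and of invasion protease and integrin genes 7 rose and 2 fell of 22 (8 and 2 adjusted over the list alone, camera adjusted p = 0.256). Among TGF-beta and SMAD targets 3 rose and 4 fell of 15 (3 and 5 adjusted over the list alone, camera adjusted p = 0.628), with a median of 0.05 although the test leaned downward. Among Wnt feedback targets 1 rose and 2 fell of 13 (1 and 2 adjusted over the list alone, camera adjusted p = 0.575), among p53 targets 4 rose and 1 fell of 18 (4 and 1 adjusted over the list alone, camera adjusted p = 0.548) and among apoptosis regulators 4 rose and 3 fell of 21 (5 and 3 adjusted over the list alone, camera adjusted p = 0.575). For androgen-regulated and luminal genes 0 rose and 2 fell of 12 (1 and 2 adjusted over the list alone, camera adjusted p = 0.702), for endothelial markers 1 rose and 1 fell of 8 (1 and 1 adjusted over the list alone, camera adjusted p = 0.792) and for neuroendocrine markers 0 rose and 1 fell of 10 (0 and 1 adjusted over the list alone, camera adjusted p = 0.256). With an estimated correlation, the adjusted p of each of these lists was 0.798.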

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

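Of the 8 tests of explanations below, the one on genes that fell in DU145 was fixed before its result was seen, and the other 7 were chosen after the result or closely related results had been seen. In PC3, 967 genes fell with the scrambled mimic and rose with miR-224 against it, where independent calls would give 243. In 50 simulated data sets of unchanged groups with shared scrambled arrays, 0.16 of 18377 genes on average were called in opposite directions, either way round. With no group changed hardly any gene passes, so that count cannot tell how many of the 967 come from the shared arrays. Chance values of the shared scrambled arrays are argued against, because the 1694 genes that fell with the scrambled mimic in DU145, on other arrays, had a median of 0.25 with miR-224 in PC3, while random lists matched on level lay between -0.01 and 0.01. A narrower spread of values on the scrambled arrays is argued against for the rise with miR-224, since 95.8% of the 967 genes (926) still rose after quantile normalization and the median went from 0.48 to 0.46, and stays open for the fall with the scrambled mimic, where 644 still fell (median -0.43 to -0.36) and 65.0% (629) passed both comparisons. Against untransfected cells 71 of these genes were higher and 10 lower with miR-224, and 175 also rose with miR-452 against the scrambled mimic. An action of the scrambled sequence on its own targets, which both mimics lack, would raise such genes with miR-452 too. It stays open, since genes not passing there may still have risen. No biological explanation was tested further.

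Interferon response genes rose with miR-452 in PC3 and the change differed from DU145, by a median of 0.74 over the list. A general response to transfected double-stranded RNA is argued against, since the list's median against untransfected PC3 cells was -0.025 with the scrambled mimic and -0.018 with miR-224, with 1 and 0 members higher by limma, beside 0.67 with miR-452 and 23 of 29 higher. One aberrant miR-452 array is argued against by 19 members passing without either of them, and a difference in spread between arrays by 22 passing after quantile normalization. A response of PC3 cells to the miR-452 mimic that DU145 cells lack, either to its sequence or to its preparation, is a hypothesis that the design cannot split further. The mimics' purity was not analysed here.

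Mitosis genes were lower with the scrambled mimic than in untransfected PC3 cells, with a list median of -0.36. A narrower spread of values on the transfected arrays, which acts by expression level, is argued against as the whole cause, because the median lay at percentile 0 of 10000 random lists matched on level, whose central range was -0.21 to -0.05, and after quantile normalization it was -0.25 against -0.10 to 0.05. One aberrant untransfected array is argued against for the direction, since the median was -0.31 without untransfected b, although the number of members passing by limma went from 22 to 0 there and to 4 without scrambled c. In DU145 the mitosis median of -0.37 also lay at percentile 0 of its matched lists, while the DNA replication and G1/S median lay at percentile 36.8. No biological explanation was tested, and a slower cell cycle after transfection, or a difference in density or handling between transfected and untransfected dishes, could account for the values.

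The change with miR-224 against the scrambled mimic differed between PC3 and DU145 for 212 genes by the interaction test. Among the named genes the difference, PC3 minus DU145 on the log2 scale, was 1.52 for DUSP6, 1.22 for TBXAS1, 1.13 for ELK3, 1.01 for PMAIP1, 0.97 for RAB18, 0.94 for MSMO1, 0.75 for ENTPD7, 0.62 for CLDN1 and 0.59 for FBXO27. It was -1.58 for CALB1, -1.49 for CTH, -1.43 for THBS1, -0.86 for DPYSL2 and -0.71 for ALDOC. The list medians that differed by camera were -0.095 for DNA replication and G1/S, -0.11 for hypoxia and glycolysis and -0.19 for mitosis, none of which passed with an estimated correlation (adjusted p = 0.638 for each).

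With miR-452 the change differed between the lines for 114 genes. The named ones were MX1 (1.91), IFI44L (1.63), OAS1 (1.57), EPCAM (1.45), IFITM1 (1.44), IL13RA2 (1.32), OAS2 (1.30), NT5E (1.27), IFI44 (1.16), ARB2BP (1.16), IFIT1 (1.14), CD68 (0.99), WDR54 (0.83), C12orf75 (0.71) and EGR1 (0.68), where PC3 minus DU145 was positive, and RELN (-1.10), MLLT11 (-1.01) and SLC7A11 (-0.84), where it was negative. By camera the interferon list differed by a median of 0.74, and by 1.00 against untransfected cells (adjusted p = 1.51e-34, and adjusted p = 0.023 with an estimated correlation, 22 of 29 members passing). The epithelial list differed by 0.26 and the immediate early and heat shock list by 0.32, each at adjusted p = 0.195 with an estimated correlation. The invasion list differed by 0.17 (camera adjusted p = 0.0188, and adjusted p = 0.195 with an estimated correlation), with 5 members higher adjusted over the list alone, and the mesenchymal list by 0.12 (0.049, and adjusted p = 0.404 with an estimated correlation) with 1 member higher. The ATF4 list had a median of -0.0058 and a mean of -0.09, with 1 member lower, the reported miR-452 targets a median of -0.11 with 2 lower adjusted over the list alone, and the Wnt list -0.10 with 1, each at camera adjusted p = 0.049 and at adjusted p = 0.629, 0.409 and 0.195 with an estimated correlation.

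For the scrambled mimic against untransfected cells the list medians, PC3 minus DU145, were -0.13 for DNA replication and G1/S, 0.16 for hypoxia and glycolysis and 0.046 for the interferon response, and none of these passed with an estimated correlation (adjusted p = 0.764 for each). Outside the named genes, 9559 features with no symbol or several symbols were tested. Against the scrambled mimic 183 of these were higher and 287 lower with miR-224 in PC3, 29 and 38 with miR-452 in PC3, and 5 and 15 with miR-224 in DU145.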

How the results depend on the processing

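The crossed-letter block was chosen after seeing the data, and the other alternatives before. The cause of the changes below was not tested. Of the named gene results, 334 of 361 were the same after quantile normalization (15 weaker, 12 stronger), 333 of 361 with trend and robust moderation (10 and 18), 318 of 349 in the fit of all 15 arrays (6 and 25), 310 of 318 with low genes left out (0 and 8), 173 of 205 with the mean of both controls (11 and 20, with 1 reversed) and 158 of 217 with untransfected arrays as the control (26 and 20, with 13 reversed). Leaving out each array gave 2333 same, 271 weaker and 44 stronger gene results. Genes passing in neither setting were counted as unchanged whatever the sign, and a lone array after leaving out its partner was assumed to vary like the other groups. After quantile normalization the calls kept with their direction were 93.3% for miR-224 and 98.7% for miR-452 in PC3, 95.2% and 94.8% in DU145, and 59.2% and 40.8% for the scrambled mimic in PC3 and DU145. Signal near background limits what can be called for weakly expressed genes. The seed-site alternatives (longest sites alone, and genes with mid-length untranslated regions) were not run for lack of a genome sequence.

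With untransfected arrays as the control the count of genes went from 3080 to 1780 for miR-224 in PC3, from 357 to 3850 for miR-224 in DU145, from 959 to 4080 for miR-452 in PC3, from 386 to 5178 for miR-452 in DU145, and for the line differences from 212 to 942 (miR-224) and from 114 to 529 (miR-452). Of the calls against the scrambled mimic, 29.6%, 64.1%, 61% and 61.1% in the same order were kept with their direction. The correlation of the miR-452 changes between the lines went from 0.45 to 0.68, and that of both mimics' changes from 0.26 to 0.39 in PC3 and from 0.52 to 0.76 in DU145. Values that reversed were, for miR-224, RNF157 (-0.035), SFT2D2 (-0.015) and RPL13 (0.021) in PC3 and SFT2D2 (-0.63) and THBS1 (-0.12) in DU145, and for miR-452, AXL (-0.18), NT5E (-0.35), SLC7A11 (-0.022), MCM6 (-0.36), CCNE2 (-0.36) and RFC4 (-0.092) in PC3 and SFT2D2 (-0.26) and RRAGC (-0.042) in DU145. With the mean of both controls MCM6 reversed for miR-452 in PC3 (-0.016), and the counts were 1020 and 1566 for miR-224 and miR-452 in DU145 and 1963 for miR-452 in PC3. The number of gene lists past camera went from 5 to 8 for miR-224 and from 3 to 5 for miR-452 in DU145 against untransfected cells.

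In DU145 the fit of all 15 arrays called 665 genes for miR-224, 969 for miR-452, 3718 for the scrambled mimic (2172 otherwise) and 1714 between the mimics (1086 otherwise), and with trend and robust moderation the mimics called 690 and 924. With low genes left out miR-452 called 588 there. With all features, and so more tests, the counts were 100 and 8 for miR-224 and miR-452 in DU145, 595 for miR-452 in PC3, 1341 and 559 for the scrambled mimic in PC3 (2618 otherwise) and DU145, 564 between the mimics in DU145 and 74 for the line difference with miR-224. After quantile normalization they were 692 for miR-452 and 1056 for the scrambled mimic in DU145 and 322 for the line difference with miR-224.

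With the replicate letter as a block (replicate block) the counts were 1732 for miR-224 in PC3, 17 for miR-224, 4 for miR-452 and 413 for the scrambled mimic in DU145, and 1952 between the mimics in PC3 (3400 otherwise). By limma they were 0 for the line differences, with 723 genes at an unadjusted p under 0.05 for miR-224 and 597 for miR-452. Without a block, letter and mimic mix in DU145 (mimics a and c, scrambled b), the line differences and in part PC3 miR-224 (a and b beside b and c). The block costs residual degrees of freedom. Under it 278 of 361 named gene results were the same, 80 no longer passed and 3 newly passed, and of the calls against the scrambled mimic 53.9% for miR-224 and 87.2% for miR-452 in PC3 and 4.76% and 1.04% in DU145 were kept with their direction. Deviations of arrays sharing a letter correlated across genes from -0.15 to 0.27 in PC3 and -0.31 to 0.05 in DU145. With the DU145 miR-452 letters crossed the replicate block counts were 74 for miR-224, 24 for miR-452, 2428 for the scrambled mimic and 1585 between the mimics. Lists past camera with the block were 2 for miR-224, 0 for miR-452 (6 at an unadjusted p under 0.05) and 5 between the mimics in DU145. Those for miR-224 were cholesterol biosynthesis and, in place of mitosis, DNA methylation and polycomb, epithelial and G1/S lists, small RNA machinery (adjusted p = 0.0241).

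By camera with an estimated correlation 0 lists passed in each of the 8 comparisons within a line, where the preset correlation gave 3 for miR-224, 7 for miR-452, 4 for the scrambled mimic and 7 between the mimics in PC3, and 5, 3, 6 and 3 in DU145. At an unadjusted p under 0.05, 2 lists were below it for miR-452, the scrambled mimic and between the mimics in PC3 and 0 in the other 5. By fry 2 lists passed for miR-224, 2 for miR-452, 2 for the scrambled mimic and 6 between the mimics in PC3, and 0 in each DU145 comparison, with 5, 5, 8 and 6 at an unadjusted p under 0.05 for miR-224, miR-452, the scrambled mimic and between the mimics.

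Leaving out each array in turn gave 1163 to 2973 genes for miR-224, 469 to 847 for miR-452, 82 to 2944 for the scrambled mimic and 1642 to 3816 between the mimics in PC3. In DU145 the ranges were 82 to 968, 114 to 1211, 0 to 5649 (3705 at an unadjusted p under 0.05 for the 0, by limma) and 254 to 2152 in the same order. For the line differences they were 47 to 411 with miR-224 and 26 to 263 with miR-452.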

Other observations

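The gene groups and selections here were chosen after the data were seen. Genes that passed against all 3 other groups of their line, in the same direction, were counted for each mimic. With miR-224, 364 genes were lower than in all 3 other groups in PC3 and 130 in DU145, and 81 were so in both, where independent calls would give 2.57. They included the mitochondrial peroxidase gene PRDX3, TMEM14C, the clathrin light chain gene CLTB, C12orf57, CYRIB and NDUFA8, of which PRDX3 (-1.15 in PC3 and -1.12 in DU145), TMEM14C (-1.15 in PC3 and -1.13 in DU145) and CLTB (-1.10 in PC3 and -1.15 in DU145) are given against the scrambled mimic. In the other direction 344 genes were higher than in all 3 other groups in PC3 and 17 in DU145, and 4 were so in both, where independent calls would give 0.318. These were ABCA1 (0.66 in PC3 and 1.03 in DU145), SESN3, EIF4EBP2, a repressor of translation, and FAM222B.

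With miR-452, 296 genes were lower than in all 3 other groups in PC3 and 129 in DU145, and 60 were so in both, where independent calls would give 2.08. Among them were TMEM184C (-1.11 in PC3 and -1.12 in DU145), MCUB (-0.95 in PC3 and -1.27 in DU145), IFT22 (-1.06 in PC3 and -1.13 in DU145), SERINC1, NCS1 and COQ10B. Higher than in all 3 other groups were 143 genes in PC3 and 10 in DU145. The 2 genes higher in both, where independent calls would give 0.0778, were CDK6 (1.00 in PC3 and 0.83 in DU145), a kinase of the G1 phase, and RGS2 (0.38 in PC3 and 0.60 in DU145), a regulator of G protein signalling. Whether these transcripts carry seed sites of the microRNAs was not analysed here.

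Replication-dependent histone genes were lower with miR-224 than with the scrambled mimic in PC3. Of 55 such genes 31 fell and 0 rose by limma, with a median of -0.37, and 28 fell after quantile normalization (camera p = 1.54e-18, and p = 0.0238 with an estimated correlation). In DU145 5 fell and 0 rose (camera p = 4.48e-06, and p = 0.139 with an estimated correlation). With miR-452 5 fell and 3 rose in PC3 (median -0.14, camera p = 4.62e-07, and p = 0.111 with an estimated correlation), and 8 fell and 0 rose in DU145 (median -0.16, camera p = 1.66e-07, and p = 0.107 with an estimated correlation). Between the mimics 25 histone genes were lower with miR-224 than with miR-452 and 0 higher in PC3 (p = 0.0654 with an estimated correlation), and in DU145 0 were lower and 1 higher, with a median of 0.05. Against untransfected cells 31 fell and 2 rose with miR-224 in PC3 (p = 0.0192 with an estimated correlation) and 23 and 4 with miR-452 (median -0.17, camera p = 0.000104, and p = 0.192 with an estimated correlation), while in DU145 5 fell and 3 rose with miR-224 (camera p = 0.314) and 17 and 5 with miR-452 (camera p = 0.0994). The family stood at a median of 0.08 with the scrambled mimic there (camera p = 0.0145, and p = 0.365 with an estimated correlation). Of 218 small nuclear, small nucleolar and vault RNA genes 61 fell and 6 rose with miR-224 in PC3, with a median of -0.18 (camera p = 2.39e-11, and p = 0.173 with an estimated correlation), and 14 fell and 0 rose in DU145 (median -0.04, camera p = 0.000948, and p = 0.186 with an estimated correlation). With miR-452 3 fell and 1 rose in PC3 (camera p = 0.0177, and p = 0.589 with an estimated correlation), and 13 and 1 in DU145 (camera p = 0.6). These counts depend on the control. Against untransfected PC3 cells 66 fell and 0 rose with miR-224 (p = 0.0706 with an estimated correlation), 44 fell and 2 rose with miR-452 (p = 0.458) and 35 fell and 4 rose with the scrambled mimic (p = 0.702). In DU145 the falls and rises were 45 and 2, 36 and 10, and 21 and 16 in the same order.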
